A study of Rattus norvegicus with 8 samples.

How the data were processed

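m6A-enriched RNA was profiled by MeRIP-seq, in which fragmented RNA is pulled down with an antibody against N6-methyladenosine (m6A) and sequenced beside an unenriched input. The cells were primary rat vascular smooth muscle cells (VSMCs) that overexpressed Mettl3, the catalytic subunit of the m6A methyltransferase, or carried a vector control. Titles assigned the 8 libraries to 4 groups of 2, an m6A immunoprecipitation (IP) group and an input group for each condition. Nothing in the labels says whether the 2 libraries of a group came from separate cell isolations. Per the labels' protocols, total RNA was fragmented with zinc, a part was kept as input, stranded libraries were made from the rest after m6A pulldown, and ribosomal cDNA was removed. Reads were trimmed with Trimmomatic 0.36, per the submitters' processing notes. The aligner, the genome build, the peak caller's settings and the use of the input libraries are not given in the sources used here; region names in the file begin with diffreps, the name of a program for differential enrichment between groups.

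The 2 tables used here hold the authors' own comparison of Mettl3 overexpression with vector, one for regions with higher and one for regions with lower signal, per the file headers. Each row gives a region, a transcript and gene name, a fold, a p-value, an FDR and a score. The deposited fold is a ratio that is above 1 in both tables, with the direction in a separate column; the smallest is 4. The deposited p-value is under 0.05 in every row, and the deposited FDR is that p-value adjusted over the regions the authors tested. The score deposited beside them equals the −log10 of the p-value. No value per library was used here, so no replicate spread, library size, count model, batch check or paired fit could be computed, and the depth behind each region is unknown. The test behind the authors' p-values is not given in the sources used here, so whether they take the spread between libraries into account is unknown; with 2 libraries per group, any such spread may be technical.

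A change was taken to pass when the authors' FDR was under 0.05, a threshold fixed before the data were examined, together with 13 gene lists and the rule for named genes. The rule named Mettl3 and Sgk1, the 10 largest passing folds in each direction whose gene symbol does not begin with LOC, RGD or AABR, the longest region and the largest fold of each table, and up to 4 passing genes per list, by smallest p. The design had planned tests per library, with counts of the authors' calls where only a comparison table was at hand, and the latter applied. RNA abundance in the input libraries, peak sets per condition, position within transcripts, sequence motifs and the relation of m6A to RNA change were not analysed here. For the gene lists only counts are given: p-values of unlisted regions were not used here, so no count adjusted over the list alone could be made. The tests that follow were not planned and were chosen after the data were seen. Whether each list was split between the 2 directions unlike the other regions was tested with Fisher's exact test (two-sided, Benjamini-Hochberg over lists). The same test was run on KEGG pathways and on GO cellular component terms with at least 10 genes, as annotated in the tables, with the genes in the tables as background. The molecular function and biological process annotations were not used here.

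Gene IDs were looked up in a RefSeq gene table of assembly GRCr8 for current names only. Of 1967 rows, 1852 carried a gene ID and 1818 of these matched; 20 rows lay on another chromosome than their gene does in GRCr8. Coordinates are given as deposited, with starts counted from 1. Their build is not GRCr8, since regions reach position 248209735 on chromosome 4, where the last GRCr8 gene ends at 184404305. The tables do not say whether a region lies in a coding exon or a UTR.

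The folds were examined for the values behind them. Of the lower regions, 83.2% (1423 of 1710) had a fold with a single decimal (within 1e-06), as had 57.6% (148 of 257) of the higher regions. Such a fold arises where one condition has a mean of 0 and a constant of 0.1 was added to both means, so its size depends on that constant. A few other pairs of means also give a single decimal. An implied 0 was found for 1415 lower and 144 higher regions. For 2 of the higher ones, with at most 4 implied reads, that 0 is doubtful. Under this reading, 95.2% of the lower regions' vector means under 6 lay within 0.015 of a multiple of 0.503, where chance gives 5.96%. Likewise 96.7% of the higher regions' overexpression means under 6 lay that close to a multiple of 0.123, where chance gives 24.4%. These steps were read as 1 read over a condition's 2 libraries, and numbers of reads derived from them are called implied reads, which are an inference from the folds and not values of the tables. For 10 higher regions the number of reads could not be determined. Folds with 3 reads in place of an implied 0, and ratios of implied reads without the weights and with 3 reads in place of fewer, were added after the data were seen. On 1672 simulated lower regions, both read numbers were recovered for 99.0%. That simulation was given the same steps as the decoding and held fewer reads than several named regions. Higher regions were not simulated, so the share does not cover their read numbers. The adjusted p-values pointed to 104053 tested regions: with that number, 61% of the 200 smallest p-values had a whole rank (within 0.001), against 12% for the next best number. The decoding, the number of tests and the permutation test were tested on simulated data. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used. Intervals are exact (Clopper-Pearson) 95% binomial intervals and cover counting error only.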

Results

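The study asked how forced expression of Mettl3, the enzyme that writes most m6A on messenger RNA, changes the m6A landscape of primary rat VSMCs, the contractile cells of the arterial wall. The study had 4 groups of 2 MeRIP-seq libraries, IP and input from overexpressing cells and from vector control cells. What was examined is the authors' list of regions whose m6A IP signal differed between the conditions. The depth of each library is unknown, and no spread between replicates can be given for any region. Whether the fold was corrected for input is not given in the sources used here, so a change in m6A signal is not separated from a change in the amount of the RNA.

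In the authors' deposited table, more regions were lower than higher in Mettl3-overexpressing cells. At an adjusted p under 0.05, 223 regions in 212 genes were lower and 52 regions in 50 genes were higher in the authors' deposited table. Lower regions made up 81.1% of these 275 regions (95% interval 76.0 to 85.5%). All regions of the authors' deposited table, taken at an unadjusted p under 0.05 and a fold of at least 4, numbered 1710 lower and 257 higher, or 86.9% lower (85.4 to 88.4%). The adjusted p-values imply 17361 tested regions up to the largest listed p, of which the listed ones are 11.3%. Unlisted regions may also have passed, and their direction is unknown. Both shares therefore describe the listed regions only. The median fold of the passing regions was 51.4 for lower and 61.3 for higher regions in the authors' deposited table. Of the passing regions, 148 lower and 33 higher ones had a fold with a single decimal, the form a mean of 0 in one condition would give, and the size of such a fold depends on the constant added to 0. With 3 reads over both libraries in place of an implied 0, and the weights of reads in the folds kept, these medians were 14.99 for lower and 5.49 for higher regions. Among all deposited regions, passing or not, with an implied 0 in one condition, lower ones started at 4 vector reads. The higher ones, but for 2 whose implied 0 is doubtful, started at 18 overexpression reads. Over all deposited regions, minimum implied means from 2.5 to 15 left between 75.1% and 84.7% lower, but such means carry the weights of reads. A minimum of 18 reads against 0, the start of the higher ones, left 19 lower against 142 higher (11.8% lower). That minimum counts reads without the weights, but equal reads are equal support only at equal depth, which is unknown. The 18 was read from the higher regions with an implied 0, of which it kept 142 of 144. Lower ones had a median of 6 reads, so the reversal was built into that cut. The 2 kinds of minimum also used different regions, all deposited ones for means and only those with an implied 0 for reads. Which direction holds the majority at equal support is thus not settled here. A vector read was weighted 4.09 times an overexpression read in the folds, and whether this weight matches the libraries' depth was not analysed here.

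**Figure D1:**
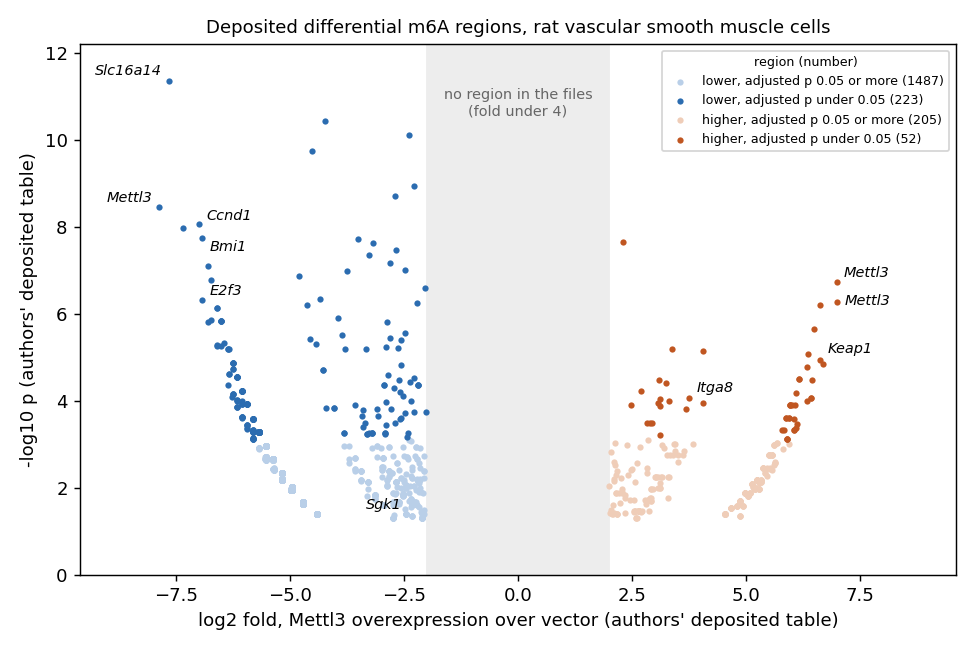
Each point is 1 of 1967 regions in the authors' deposited table; the x axis is the log2 fold of Mettl3 overexpression over vector and the y axis is the −log10 of the p-value, both without units. Blue points are lower (1710) and orange points higher (257) in overexpressing cells, dark where the adjusted p is under 0.05 (223 and 52); the outer arcs are the folds with a single decimal, and no region has a fold under 4.

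Mettl3 itself, the overexpressed gene, carried regions in both directions. In the authors' deposited table, 2 Mettl3 regions (transcript NM_001024794) were higher in overexpressing cells. One lay on chromosome 15 from 32531163 to 32531328, with a fold of 127.7 and an adjusted p of 9.73e-05 in the authors' deposited table. The other lay from 32523366 to 32523582, with a fold of 128.8 and an adjusted p of 0.000227 in the authors' deposited table. These were the largest folds among the higher regions, and the number of reads behind them could not be determined. Another Mettl3 region, of 21 bp, from 32520500 to 32520520, was lower, and its fold of 233.6 (adjusted p = 3.50e-06) was the largest of the authors' deposited table. That fold has a single decimal, and the means read from it gave the overexpressing cells an implied 0, against 46 implied vector reads. With 3 reads in place of that 0 the fold was 62.7 under the weights of the folds, and the ratio of reads alone was 15.3.

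Sgk1, the serum- and glucocorticoid-regulated kinase named in the series title, had 1 region in the authors' deposited table, and it was listed as lower in overexpressing cells. This region of transcript NM_019232 lay on chromosome 1 from 25658055 to 25658190 (136 bp), with a fold of 5.21 and a log2 value of -2.38 in the authors' deposited table. Its p was 0.0129 and its adjusted p 0.177 in the authors' deposited table, so it did not pass. The implied support was 11 reads in the vector libraries and 8 in the overexpression libraries, in which a read weighed less, a ratio of reads of 1.38.

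Both passing genes of the cell cycle list, Ccnd1 and E2f3, stood among the 10 lower regions with the largest folds. Ccnd1 (cyclin D1, which drives entry into S phase) had a lower region at chromosome 1 from 224969562 to 224969658. Its fold was 126.8 and its adjusted p 7.28e-06 in the authors' deposited table. E2f3, a transcription factor of S-phase genes, had a lower passing region at chromosome 17 from 37715922 to 37716320. That region had a fold of 122.1 and an adjusted p of 0.000211 in the authors' deposited table. Bmi1, a Polycomb repressor, had a lower region at chromosome 17 from 87091362 to 87091418, with a fold of 121.9 in the authors' deposited table. Slc16a14, a monocarboxylate transporter family member, had the smallest p of all regions (4.33e-12) and a fold of 202.4 in the authors' deposited table; it lay on chromosome 9 from 92238062 to 92238202. The remaining large folds among lower regions of the authors' deposited table were 162.6 for MGC94335 (now Maip1), 112.0 for N4bp1, 111.8 for the zinc-finger gene Zfp217, 106.8 for Pik3ip1, a negative regulator of PI3K, and 106.5 for Cyp2j3. The MGC94335 region was only 6 bp long, and Cyp2j3 belongs to a family of similar genes, so its reads are uncertain. All of the lower regions named in this paragraph had an implied mean of 0 in the overexpressing cells, against 21 to 40 implied vector reads. With 3 overexpression reads in place of 0 and the weights of the folds, the fold was 54.5 for Slc16a14, 34.1 for Ccnd1 and 32.7 for E2f3 and Bmi1; the ratios of reads alone were 13.3, 8.33 and 8.

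Outside Mettl3, the largest folds among the higher regions were those of Vom2r30, Taok2, Keap1 and Taok1. In the authors' deposited table, Taok2 and Taok1, kinases that act upstream of MAPK and Hippo signalling, rose with folds of 99.4 and 89.6 (adjusted p = 0.000259 and 0.00074). Their regions lay on chromosome 1 from 205295106 to 205295197 and on chromosome 10 from 62296958 to 62297161. Keap1, the adaptor that targets the oxidative stress factor Nrf2 for degradation, had a higher region at chromosome 8 from 22305942 to 22306240. Its fold was 99.4 (adjusted p = 0.0025) in the authors' deposited table. Tsc22d4, Atad2, Plekhb1 and Pragmin (now Prag1) had higher regions with folds of 87.1, 85.9, 85.9 and 82.2 in the authors' deposited table. Atad2 also had 2 lower regions there, 1 of which passed, and Pragmin had 1 lower region that did not pass. The fold of 103.1 for Vom2r30 and the longest higher region, 474 bp in Olr1075 with a fold of 66.2, are uncertain in the authors' deposited table, because both genes belong to large receptor families of similar sequence. Each of these regions outside Mettl3 had an implied vector mean of 0, and with 3 vector reads in its place and the weights of the folds, the fold was 6.52 for Taok2 and Keap1, 5.87 for Taok1, 6.77 for Vom2r30 and 4.32 for Olr1075. The ratios of reads alone were 26.7, 24, 27.7 and 17.7. The longest lower region of the authors' deposited table spanned 673 bp of Tenm4, with a fold of 4.83 and an adjusted p of 0.00485; it rested on 35 implied vector reads against 29 overexpression reads, a ratio of reads of 1.21.

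Genes of the m6A machinery held 6 passing regions, of which 3 lay in Mettl3, the overexpressed gene, and 3 in other genes. Of its 26 members, 4 genes had a lower region that passed and 1 a higher one, Mettl3 being in both counts, and 22 had none. Besides Mettl3, the lower regions lay in Ythdf2, a reader that promotes decay of m6A-marked RNA (fold 51.4), Rbm15b, an adaptor of the writer complex (fold 51.3), and Zc3h13, which keeps that complex in the nucleus (fold 14.1), all in the authors' deposited table. Their adjusted p were 0.036, 0.036 and 0.0377 in the authors' deposited table. The Ythdf2 and Rbm15b regions rested on 10 implied vector reads each against 0, and the Zc3h13 region on 13 against 3. With 3 reads in place of 0 and the weights of the folds, the fold was 13.6 for Ythdf2 and Rbm15b, and the ratio of reads alone was 3.33. Zc3h13 also had 1 higher region and another lower one in the authors' deposited table, neither of which passed.

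Few genes of smooth muscle phenotype and growth signalling passed. Of the 20 contractile genes, 1 had a higher passing region and 19 had no passing region. The 1 gene was Itga8, the integrin alpha-8 chain abundant in smooth muscle. Its region had a fold of 13.5 (adjusted p = 0.0112) in the authors' deposited table, from 66 implied overexpression reads against 1 vector read. Of the 30 matrix genes, 1 had a lower passing region, Col1a1, a chain of type I collagen. The fold was 66.5 (adjusted p = 0.00831) in the authors' deposited table. That region was 23 bp long and rested on 13 implied vector reads against 0. In the cell cycle list 2 of 35 genes had a lower passing region, Ccnd1 and E2f3. The SGK1, PI3K, mTOR and FoxO list had 1 of 28 genes with a lower passing region, Pik3r1, the p85-alpha subunit of PI3K. The Pik3r1 region had a fold of 5.34 (adjusted p = 0.0378) in the authors' deposited table. It rested on 27 implied vector reads against 20 overexpression reads, a ratio of reads of 1.35. The Hippo, Wnt and Notch list had 1 of 24 genes with such a region, the Notch ligand Jag1. The Jag1 fold was 51.3 (adjusted p = 0.036) in the authors' deposited table. Among the 24 chromatin regulators 1 had such a region, the acetyltransferase Crebbp, with a fold of 61.2 (adjusted p = 0.0359) in the authors' deposited table. The Jag1 and Crebbp regions rested on 10 and 12 implied vector reads against 0. With 3 reads in place of 0 and the weights of the folds, the fold was 17.7 for Col1a1, 13.6 for Jag1 and 16.4 for Crebbp, and the ratios of reads alone were 4.33, 3.33 and 4. No gene passed among 19 synthetic smooth muscle genes, 28 TGF-beta and BMP genes and 25 inflammation genes, which had 2, 2 and 3 genes with a region in the authors' deposited table.

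Markers of other cells of the arterial wall, 9 endothelial, 8 leukocyte and macrophage and 7 adventitial fibroblast genes, had no region in the authors' deposited table; these lists are short, and the count says nothing of other genes that such cells express. Over all lists, 40 of 283 genes had a region in the authors' deposited table, 38 of them a lower one and 5 a higher one, and 11 passed. None of the 10 lists with a region was split between directions unlike the other regions by Fisher's exact test (two-sided, smallest p = 0.102). No list had an unadjusted p under 0.05 in this test. It used all deposited regions, of which 86.9% were lower, and the lists held from 2 to 12 regions. At these sizes a tilt to lower regions could hardly be detected.

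**Figure D2:**
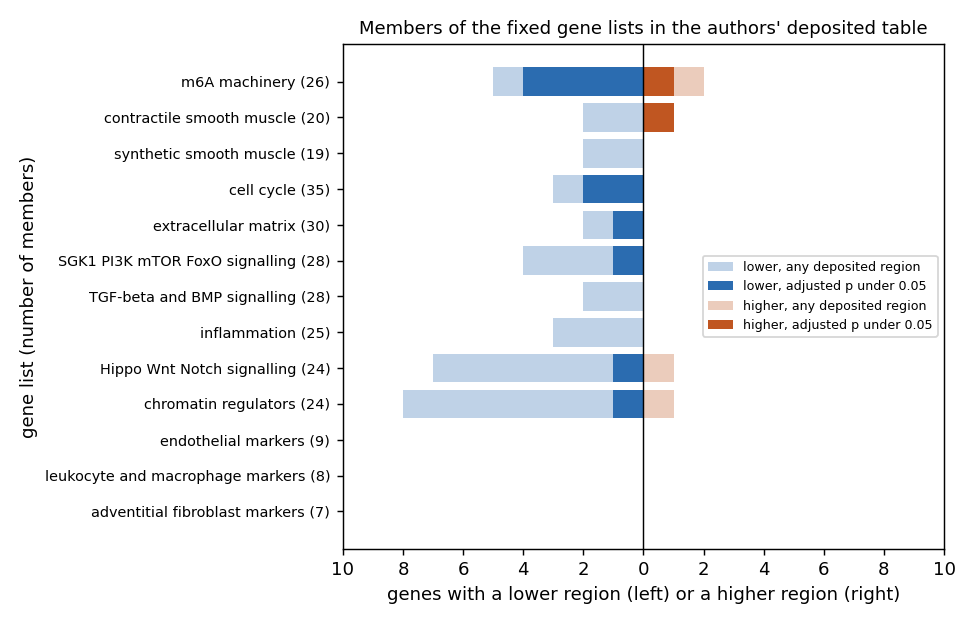
Bars give, for each gene list fixed before the data were examined (number of members in brackets), the number of genes with a lower region (left of 0) or a higher region (right of 0) in the authors' deposited table; pale bars count any region and dark bars those with an adjusted p under 0.05. Counting any region, lower genes outnumber higher ones in every list with a region, up to 8 against 1 for the chromatin regulators; among passing regions the contractile list has 1 higher and 0 lower genes, and the 3 lists of other cell types are empty.

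No annotated pathway was found to set the passing genes apart from the other listed genes. Of 81 KEGG pathways, none was called over- or under-represented among the 85 passing genes that carry a pathway. They were compared with the other annotated genes of the authors' deposited table (540 in all, Fisher's exact test, two-sided, Benjamini-Hochberg, 0 at an unadjusted p under 0.05). All of these genes were listed at an unadjusted p under 0.05, so enrichment against every tested gene was not examined. Small terms could hardly show under-representation: the 14 genes of inositol phosphate metabolism, 0 of them passing, gave p = 0.142 (Fisher's exact test). Of 89 GO cellular component terms, none passed Fisher's exact test either (two-sided; smallest adjusted p = 0.598), and 3 had an unadjusted p under 0.05. The split between genes with only higher and only lower regions gave no term after adjustment, with 1 pathway and 3 component terms at an unadjusted p under 0.05. Term size limits this split too: Wnt signalling, with 0 only higher and 16 only lower genes, gave p = 0.238 (Fisher's exact test). The excess of lower regions was spread over the genome: between 82.5% on chromosome 17 and 92.8% on chromosome 8 were lower, and no chromosome differed from the others (Fisher's exact test, two-sided, 21 chromosomes; smallest p = 0.0597, adjusted p = 1).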

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

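At an adjusted p under 0.01, 94 lower and 18 higher regions passed (83.9% lower), and counting genes in place of regions gave 212 lower and 50 higher (80.9% lower). A minimum log2 change of 1 removed nothing, because every fold is at least 4. The other settings were chosen after seeing the data: taking all regions of the tables gave 1710 lower and 257 higher (86.9% lower). Leaving out folds with a single decimal gave 75 lower and 19 higher. Requiring an implied mean of at least 10 gave 62 and 10 (86.1% lower), and requiring both region edges on a 20 bp grid gave 73 and 14. Lower regions were the majority in each of these settings, all of which kept the weights of reads in the folds. A minimum on implied reads, also chosen after seeing the data, turned the majority. Among all deposited regions with an implied 0 in 1 condition, at least 18 reads left 19 lower and 142 higher (11.8% lower). That minimum was the start of the higher regions, so the turn was built in and does not settle the majority. The stricter threshold and the subsets hold fewer regions by construction; beyond that the cause was not tested. Members of the fixed lists numbered 10 with a lower and 2 with a higher region; an adjusted p under 0.01 left 4 and 1, and all regions gave 38 and 5. Of the 31 named regions, 10 no longer passed at an adjusted p under 0.01, and 1, in Sgk1, passed only at the unadjusted p. No paired analysis was possible because the tables hold no value per library; for the same reason leaving out a library, another normalization, and the planned filter and pseudocount on values per library were not run, nor was the IP without input. The alternatives for peak sets, peak location, motifs, list background and RNA change were not run either. With 3 reads in place of an implied 0, also chosen after seeing the data, the median fold of passing regions went from 51.4 to 14.99 for lower and from 61.3 to 5.49 for higher regions. Library depth is unknown, and 398 of the 1710 lower regions rest on 4 implied vector reads against 0.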

Other observations

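All tests in this part were chosen only after the results they bear on had been seen.

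Some genes held many regions, counted over all regions of the authors' tables whether or not they passed; those named here are some of them and were chosen after their values were seen. Macf1, a linker of actin and microtubules, had 6, all lower; Dst (dystonin) had 5 lower and 1 higher; Dsp (desmoplakin) and Nav3 had 4 lower each; and Kalrn had 2 in each direction. A hypothesis that regions of 1 gene change together was tested over the 192 genes with at least 2 regions. All regions shared 1 direction in 147 of them, against a mean of 143.4 with permuted directions (permutation test, two-sided, 100000 permutations, p = 0.525). The other 45 genes held regions in both directions, so regions of 1 gene did not always change together. A weaker tendency is left open, since an excess of lower regions alone gives about this number.

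The excess of lower regions among the listed regions, in cells with more Mettl3, is the pattern to look at again. The steps in the folds imply that a read in the vector libraries was weighted 4.09 times a read in the overexpression libraries, so lower calls reach down to 4 implied vector reads against 0, while almost every higher call with 0 in vector needed at least 18 reads. Neither sampling noise from few vector reads nor this weight can be told apart from a change in the cells. Among regions with an implied mean of at least 10, 81.1% were lower (73 against 17, 95% interval 71.5 to 88.6%). That mean carries the weight, and lower regions entered from 20 reads and higher ones from 83. Among regions with at least 10 implied reads against 0, 52.2% were lower (155 against 142, 46.3 to 58.0%). Lower ones entered there from 10 reads and higher ones only from 18, so neither share is free of the weight. At a minimum of 18 reads against 0, 11.8% were lower (19 against 142, 7.26 to 17.8%). That cut counts reads without the weight, but equal reads are equal support only at equal depth. It was also set at the fewest reads of nearly all the higher ones, so the low share was built in. Library sizes, which would tell whether the weight reflects depth, were not analysed here. A true loss of m6A and a fall in RNA abundance also stay open, untested, since no input value was used.

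Mettl3 carried its 2 most strongly higher regions and the most strongly lower region of the tables. Region edges fall on a 20 bp grid for 43.0% of starts and 46.3% of ends. Both edges were off the grid for 2 of the 2 higher Mettl3 regions, as whole exons read from an overexpressed cDNA would show, but 32.4% of all regions have this form and no exon map of this build was used, so RNA from the construct cannot be told apart from methylation there. The lower region ends on the grid and had 46 implied vector reads against 0. A fall of the endogenous transcript is a biological alternative that was not tested.

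The adjusted p-values imply 104053 tested regions, of which 17361 (16.7%) reached the largest p in the tables. The 1967 regions in the tables are 11.3% of those, and the direction of the rest is unknown. The commonest fold among lower regions, 21.1, occurs 324 times, and 256 regions are shorter than 50 bp.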
